A study of Arabidopsis thaliana with 12 samples.

How the data were processed

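RNA from whole 3-week seedlings of Arabidopsis thaliana Columbia-0 was measured on 12 arrays, 4 each of wild type, 35S:MYB106SRDX and 35S:WIN1SRDX. Per the labels' protocols, plants were grown at 23 °C with 16 h of light and 8 h of darkness on MS agar with 1% sucrose, total RNA was isolated with a column kit, and 1 µg of it was labelled with Cy3 for 1-colour hybridisation. The arrays were Agilent 44K designs read with Agilent Feature Extraction 9.1.3.1, per the file headers.

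The deposited scanner files give, for each spot, an intensity already corrected for background by Feature Extraction (the processed signal), together with the raw median intensity, the local background and flags for outlying spots, saturated spots and signals well above background, per the file headers. Each array held 37685 non-control spots of 37478 probes and 1417 control spots. The authors' value table was set against the scanner intensities: in it the authors divided the processed intensity of each array by a constant, 1082.6 for MYB106SRDX, 995.6 for WIN1SRDX (995.7 for replicate 3) and 1264.0 for wild type, with 100.0% of probes within 1% of that constant on each array. Each of its values is thus a ratio of an intensity to a constant, made by the authors before deposit. They are linear and not centred, and no log was taken; why each group has a constant of its own is not given in the sources used here. The column medians of that table were 0.0698, 0.0598, 0.0652 and 0.0758 for MYB106SRDX replicates 1 to 4, 0.0977, 0.0867, 0.1366 and 0.1096 for WIN1SRDX, and 0.0996, 0.0966, 0.0993 and 0.1088 for wild type.

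From the processed signal, log2 values were taken and the 75th percentile of the non-control spots of the array was subtracted. Control spots and spots marked as outliers were left out, and the spots of a probe were averaged. Of the probes, 26236 name a locus, covering 25665 loci, of which 541 have more than 1 probe; the probe with the highest mean was used for each. Of the loci, 25449 were found in a table of RefSeq names (assembly TAIR10.1, used for names only), and 10198 have a gene symbol. The other 11242 probes name a chromosome interval (8812) or a transcript or cluster (2430) and were tested apart. A gene was tested if it lay well above background on all 4 arrays of at least 1 group, which left 20267 genes. Where a gene had several tested probes (438 genes), they gave opposite calls for 8 genes in MYB106SRDX against wild type, 2 in WIN1SRDX against wild type and 4 between the lines. No pair of arrays held identical values.

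Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with all 3 groups in a single fit, which leaves 9 residual degrees of freedom and a shared estimate of spread, and Benjamini-Hochberg adjustment over all tested genes of a comparison; "passed" means adjusted p under 0.05. A gene not well above background on any array of a group is given as a bound: the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the lowest signal well above background and the gene's own signal. Where a gene was above background on only some arrays of a group, its fold change rests partly on signals near background.

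Before the data were examined, 19 gene lists with 329 members were fixed: cutin, wax, suberin, cuticle regulators, trichome, stomata, flavonoid, photosynthesis, salicylic acid defence, jasmonate, abscisic acid and drought, expansins, cell cycle, circadian clock, aliphatic glucosinolate, touch and wounding, senescence, root markers and flowering markers. The groups, the tests, the lists, the rule for named genes and all processing alternatives other than those said to be added were fixed at that time. On the array were 328 members; 1 more was left out because its symbol disagreed with its locus. Each list was tested against all other genes with camera at its preset correlation of 0.01 (adjusted over 19 lists), again with an estimated correlation, and with fry, which asks whether the genes of a list move on balance in one direction and does not compare them with other genes.

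Genes were named by a rule: the 8 largest rises and 8 largest falls that passed, had a symbol, lay well above background on all arrays of both groups and showed no overlap between the arrays of the groups; MYB106, WIN1, MYB16, SHN2 and SHN3; the 4 members with the lowest p of the cutin, wax, suberin, cuticle regulator and trichome lists; the 3 with the lowest p of every other list with at least 3 members passing; and the 8 genes lower and 8 higher in both lines with the largest smaller change. Named outside that rule, after their values were seen, were SUP, AP3, LHY, CCA1, the genes of the second iron, ferritin and second root lists with bHLH38 and BHLH100, IRT1 and AG, and some list members: NRT2.1, GSTF11, BCAT4, SEP3, PI and TOC1 in MYB106SRDX against wild type, MCM5, TMM, UGT75C1 and AGL24 in WIN1SRDX against wild type, and MYB5, HDG2, HDG1, MYB41, PR5, WRKY70 and RBCS2B between the lines. Of the genes the rule names, 1 is not reported here.

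The comparisons with wild type share their 4 control arrays. Their overlap is therefore given with 20 simulations without group differences, in which all arrays were redrawn with independent genes. It is also given with the overlap of independent lists, and with 6 partitions of the control arrays. The 3 slides each held 4 arrays and all 3 groups, 1 scan date covered all arrays, and 0 genes passed a test for a slide effect (limma, adjusted as above); values with the slide as a block and within slides are given beside the counts.

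The pipeline was tested on simulated data for MYB106SRDX against wild type over 20267 genes with 200 changed genes: 49% of those changed 2-fold and 83% of those changed 4-fold were recovered, 3.65% of called genes were false, 0 genes were called in an unchanged comparison, and the list that had been shifted was called with no other list. The simulated genes were drawn independently, and far fewer changed than in the data. In the data the estimated correlation within a list reached 0.782. The simulation therefore cannot show how often camera at its preset correlation calls lists wrongly here.

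Alternatives tried were another background correction (normexp with offset 50 on the median signal, added after seeing the files because they give no mean signal), quantile normalization, the authors' value table, other filters on dim probes, keeping marked spots, other rules for several probes of a gene, trend and robust settings of eBayes, array quality weights, only the groups compared, the slide and the replicate number as blocks, a 2-fold threshold, a floor at the background limit (added), leaving out each array, and leaving out 2 arrays of doubt (added). Array measures were compared by exact permutation tests with SciPy 1.17.1; other tools were Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, the R package data.table (version 1.17.8) and matplotlib 3.10.9. No genome sequence was used, so positions of probes within transcripts were not analysed here.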

Results

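Transcript levels were measured in whole seedlings of Arabidopsis thaliana, accession Columbia-0, at 3 weeks of age. The 12 samples fell into 3 groups of 4: wild type, 35S:MYB106SRDX and 35S:WIN1SRDX. Each transgene is driven by the constitutive 35S promoter and fuses a transcription factor to SRDX, a short repression domain derived from the SUPERMAN (SUP) protein that turns an activator into a repressor. MYB106 is a MYB factor known from trichome and epidermal development, and WIN1 (also SHN1) is an AP2/ERF factor known from cuticle formation. The contrasts therefore ask which transcripts differ from wild type when a repressor form of either factor is produced, and where the lines differ from each other. All 12 RNA samples were hybridised to 1-colour Agilent arrays, on 3 slides that each held all 3 groups.

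Between 59.3% and 64.2% of the non-control spots of an array lay well above background, and no spot was saturated. The median spot intensity was 76.7 ± 7.86 (SD, n = 4) in MYB106SRDX, 112.4 ± 22.3 (SD, n = 4) in WIN1SRDX and 133.7 ± 7.0 (SD, n = 4) in wild type. It was lower in all 4 MYB106SRDX arrays than in any wild-type array (exact two-sided permutation test, p = 0.0286, the smallest that 4 against 4 arrays can give; 0.0572 after adjustment over 6 such tests). The share of spots well above background was 60.4% ± 0.858 (SD, n = 4) in MYB106SRDX and 62.9% ± 1.11 (SD, n = 4) in wild type, with the same exact permutation p = 0.0286. Arrays of a group correlated at 0.926 to 0.994, and the median SD of a gene was 0.31 in MYB106SRDX, 0.28 in WIN1SRDX and 0.14 in wild type on the log2 scale. The labels describe several seedlings harvested from a plate for each sample and name no separate cultures, so the p-values measure only the spread between these samples, which may be technical; the number of arrays limits the precision. Expression values below are log2 signals relative to the 75th percentile of the array, and fold changes carry their standard error (SE) from the fit.

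The MYB106 probe read 4.17 ± 0.94 (SD, n = 4) in MYB106SRDX, -2.29 ± 0.65 (SD, n = 4) in wild type and -3.89 ± 0.89 (SD, n = 4) in WIN1SRDX. MYB106 signal thus rose by 6.46 ± 0.54 (SE) in MYB106SRDX (adjusted p = 7.56e-06), and replicate 2 of that line, at 2.77, lay below its other arrays. The WIN1 probe read 5.6 ± 0.20 (SD, n = 4) in WIN1SRDX, while it was well above background on only 2 of 4 wild-type arrays and 1 of 4 MYB106SRDX arrays. WIN1 signal rose by 13.22 ± 1.14 (SE) in WIN1SRDX (adjusted p = 4.19e-05) and differed by 0.13 ± 1.14 (SE) in MYB106SRDX (adjusted p = 0.935). Where on the transcripts these probes lie was not used here, so signal from a transgene is not separated from that of the plant's own gene. Each line was high in the probe of its own transcription factor on all 4 arrays. SUP, chosen after its values were seen, was not well above background on any wild-type array and was at least 4235-fold higher in MYB106SRDX (adjusted p = 7.29e-09) and at least 9988-fold higher in WIN1SRDX (adjusted p = 8.81e-09).

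**Figure D1:**
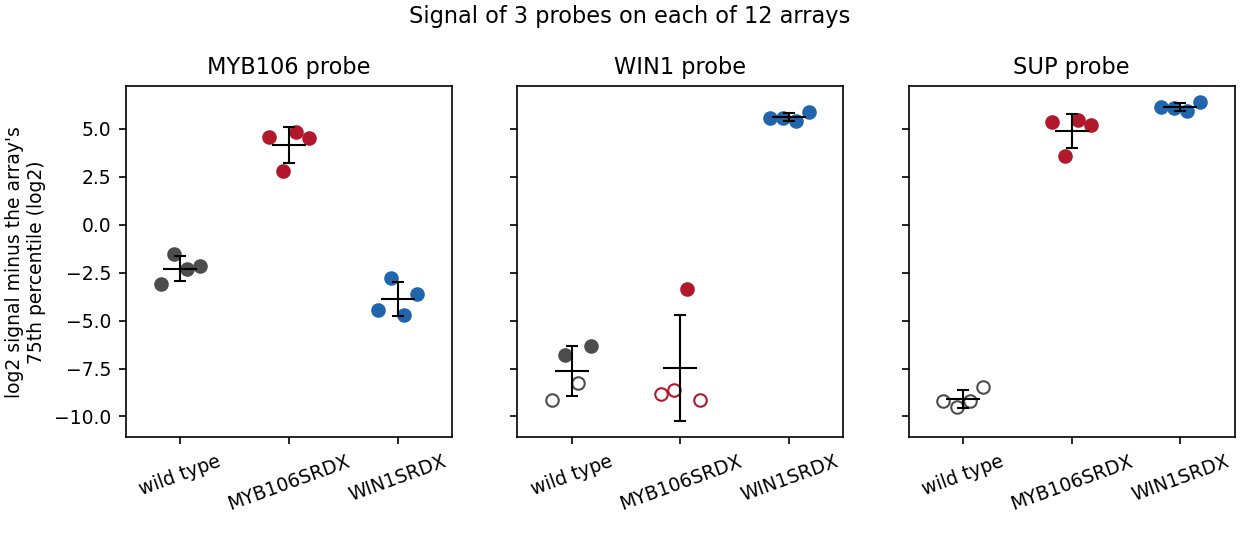
Log2 signal of the MYB106, WIN1 and SUP probes relative to the array's 75th percentile, on each of 12 arrays, with the mean and SD of each group; open circles mark arrays on which the probe was not well above background. MYB106 averaged 4.17 in MYB106SRDX, WIN1 averaged 5.6 in WIN1SRDX, and SUP was high in both lines.

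In MYB106SRDX seedlings, most cutin, wax and suberin genes, which make lipid polymers and waxes of plants, were lower than in wild type. Most flavonoid, expansin, cell cycle, trichome and root marker genes were lower too. Of the senescence genes 5 of 7 rose, and of the salicylic acid defence genes 7 of 14 rose and 2 fell. These lists were called by camera at its preset correlation, and none with an estimated correlation (lowest adjusted p = 0.0542 with an estimated correlation). GPAT8, an acyltransferase of cutin synthesis, fell by 5.98 on the log2 scale (adjusted p = 0.000666). SAG13, a senescence marker, rose by 7.93 ± 0.43 (SE) with an adjusted p of 6.17e-07.

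Of 20267 genes tested, 10587 (52.2%) differed between MYB106SRDX and wild type, 4789 higher and 5798 lower. At least 2-fold changes made up 5765 of these, 2049 higher and 3716 lower. In 52.7% of genes the arrays of the groups did not overlap at all, against 2.86% by chance. With the slide as a block, 9871 genes differed.

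The largest rises among fully measured genes were those of CYP76C2, a cytochrome P450, at 9.16 ± 0.47 (SE) with adjusted p = 4.65e-07, and ABCG40, an ABC transporter that imports abscisic acid, at 8.83 ± 0.76 (SE) with adjusted p = 8.86e-06. PXMT1, a methyltransferase, rose by 8.79, AMY1, an alpha-amylase, by 8.17, DXPS1 by 7.52, the elicitor-activated gene ELI3-2 by 7.41, and AOX1D, an alternative oxidase of mitochondria, by 7.27. The largest falls were those of DR4 (-7.17 ± 1.01, SE) and MSRB6, a methionine sulfoxide reductase (-7.0 ± 0.64, SE). MLP328 changed by -6.35, the cell wall protein gene PRP4 by -6.29, P1R3 by -6.21, SHY2, an auxin response repressor, by -6.14 and the expansin EXPA11 by -6.00.

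Of 22 cutin genes, 18 fell, none rose and 4 did not pass, with a median log2 fold change of -2.54; adjusted over the list alone, 18 fell as well. The list stood apart from other genes (camera, adjusted p = 0.00021), though not with an estimated correlation between its genes (adjusted p = 0.537 with an estimated correlation). GPAT6, which esterifies cutin monomers, changed by -2.99 ± 0.37 (SE), the fatty acid hydroxylase CYP86A8 by -3.31 and HTH, a gene that keeps organs from fusing, by -3.21. Among 22 wax genes, 16 fell and 6 did not pass (median -2.44, adjusted p = 0.000178; adjusted p = 0.528 with an estimated correlation), and 17 fell when adjusted over the list alone. The elongases KCS1, KCS9 and KCS20, which extend very long fatty acids, changed by -3.04, -1.87 and -2.57, and the dehydratase PAS2 of the same complex by -1.12. Suberin genes fell in 11 of 12 cases, with the same count adjusted over the list alone (median -4.15, adjusted p = 4.81e-05; adjusted p = 0.463 with an estimated correlation). The suberin transporter genes ABCG2 and ABCG6 changed by -3.48 and -4.80, the fatty acyl reductase FAR1 by -3.95 and the caffeoyl transferase FACT by -4.77. Root markers also fell in these seedlings (median -5.08), and the suberin fall was not separated from a change in the share of roots. Within slides 1, 2 and 3 the cutin median was -3.69, -2.92 and -2.04, the wax median -3.32, -2.15 and -1.93, and the suberin median -4.90, -3.57 and -4.16.

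Among 13 cuticle regulators, 7 fell and 1, MYB106 itself, rose; adjusted over the list alone, 7 fell and 2 rose. The list was not called (median -0.66, camera, adjusted p = 0.316, and fry, adjusted p = 0.0408). MYB106 signal, not separated from that of the transgene, enters both tests. MYB16, the closest relative of MYB106, changed by -3.95 ± 1.04 (SE, adjusted p = 0.0087), SHN2, a relative of WIN1, by -3.89 ± 1.18 (SE, adjusted p = 0.0175, above background on 3 of 4 MYB106SRDX arrays), the wax repressor gene DEWAX by -2.64 and the epidermal factor ATML1 by -2.14. MYB41 was at least 3.34-fold lower, but with another background correction it changed by -0.45 and no longer passed. SHN3 was not well above background on all arrays of any group and was not tested. Trichome genes fell in 11 of 16 cases, and in 11 adjusted over the list alone, with 5 not passing (median -1.72, -1.53 with genes below background at their bounds; adjusted p = 0.00968; adjusted p = 0.528 with an estimated correlation). The endoreduplication factor SIM changed by -1.95, the zinc finger gene GIS by -2.41 and TTG2, a WRKY factor of trichomes and seed coats, by -2.56. ETC2, a repressor of trichome fate, was at least 2.16-fold lower, a call lost under the other background correction (-0.04). The fall of trichome genes was not separated from a change in the share of roots.

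Flavonoid genes fell in 13 of 17 cases, and in 13 adjusted over the list alone (median -3.37, -2.93 with bounds; adjusted p = 0.000202; adjusted p = 0.463 with an estimated correlation). LDOX, an anthocyanin enzyme, was at least 28.6-fold lower, UGT79B1, a glycosyltransferase of anthocyanins, at least 20.1-fold lower and MYB12, an activator of flavonol genes, at least 6.99-fold lower. Of 17 expansin genes, which loosen cell walls, 16 fell, also adjusted over the list alone (median -2.0, adjusted p = 0.000202; adjusted p = 0.463 with an estimated correlation), with EXPA8 at -4.80 and EXLA2 at -2.10. Of 21 cell cycle genes, 15 fell and 6 did not pass, with 15 adjusted over the list alone (median -1.92, adjusted p = 0.00369; adjusted p = 0.678 with an estimated correlation). The mitotic kinase genes CDKB1;1, CDKB1;2 and CDKB2;1 changed by -2.41, -2.58 and -2.19. The cell cycle median was -1.95 and -2.98 within slides 1 and 2 and -0.15 within slide 3.

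Root markers fell in 14 of 17 cases, with 14 adjusted over the list alone (median -5.08, -4.05 with bounds; adjusted p = 1.12e-06; adjusted p = 0.358 with an estimated correlation). COBL9 and EXPA18, both of root hairs, were at least 43.4-fold and at least 16.7-fold lower. The nitrate transporter gene NRT2.1 rose by 3.92 (adjusted p = 0.0109). Because whole seedlings were sampled, the share of roots in each sample is part of every value.

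Senescence genes rose in 5 of 7 cases, the same 5 adjusted over the list alone (median 1.78, adjusted p = 0.00022; adjusted p = 0.0542 with an estimated correlation). ORE1 and NAP, NAC factors that promote leaf senescence, rose by 2.31 and 2.03. Salicylic acid defence genes rose in 7 and fell in 2 of 14 cases (7 and 3 adjusted over the list alone; median 1.54, adjusted p = 0.0488; adjusted p = 0.528 with an estimated correlation). This call was lost without any of 7 single arrays (adjusted p from 0.0505 to 0.0615), with no filter on dim probes (0.56, adjusted p = 0.0714), with only genes well above background on all 12 arrays (1.54, adjusted p = 0.192), with normexp (1.19, adjusted p = 0.0526), and with the mean of probes, the background floor or only the groups compared (adjusted p from 0.051 to 0.0682). CYP71A13, an enzyme of camalexin synthesis, was at least 126.5-fold higher, PBS3, which acts in salicylic acid synthesis, rose by 2.55, and the defence regulator gene PAD4 changed by -1.47. Jasmonate genes rose in 8 and fell in 3 of 24 cases (8 and 3 adjusted over the list alone; median 0.40, adjusted p = 0.276), with HEL at 2.37, HCHIB at 1.62 and ORA59 at -1.68. Abscisic acid and drought genes rose in 8 and fell in 3 of 19 (8 and 3 adjusted over the list alone; median 1.33, adjusted p = 0.119). Without replicate 2 of MYB106SRDX the list was called (1.63, adjusted p = 0.00415). ABI1, a phosphatase of abscisic acid signalling, rose by 2.05, HB-7 by 3.12 and RD29B by 3.73.

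The remaining lists were not called in MYB106SRDX. Touch and wounding genes rose in 7 and fell in 1 of 14 cases (7 and 1 adjusted over the list alone; median 1.24, adjusted p = 0.127; 1.49 and adjusted p = 0.0101 without MYB106SRDX replicate 2), with WRKY33 at 2.06, SZF2 at 1.71 and XTH22 at -2.65. Of 15 clock genes, 8 fell and 3 rose (9 and 3 adjusted over the list alone; median -0.79, mean -0.15; adjusted p = 0.308; fry, adjusted p = 0.00311), among them PRR5 at -1.46, GRP7 at -1.82 and GRP8 at -0.85. The PRR5 call was lost with marked spots kept (-1.46, adjusted p = 0.0673) and on the authors' scale (-1.51, adjusted p = 0.0785). Stomatal genes fell in 7 and rose in 1 of 18 cases (4 and 1 adjusted over the list alone; median -1.33, adjusted p = 0.115; -1.60 and adjusted p = 0.0342 without MYB106SRDX replicate 1), with the guard cell channel gene KAT1 at -2.95, ER at -1.21 and EPFL9 at -1.44. Photosynthesis genes fell in 9 and rose in 1 of 20 (9 and 1 adjusted over the list alone; median -0.30, adjusted p = 0.156; -0.42 and adjusted p = 0.0342 without MYB106SRDX replicate 1, and -0.33 and adjusted p = 0.0433 with normexp), with RBCS1B at 1.17 and the light-harvesting genes LHCB2.1 at -3.94 and LHCB2.2 at -4.34. Of 14 aliphatic glucosinolate genes, GSTF11 and BCAT4 fell (1 gene adjusted over the list alone; median -0.56, adjusted p = 0.642). Flowering markers rose in 2 (PI and SEP3) and fell in 2 (SPL3 and SOC1) of 13 cases, as they did adjusted over the list alone (median -0.37, mean 0.02; adjusted p = 0.844). In all, camera called 10 of 19 lists, none with an estimated correlation, and 14 of the 35 ways to split the 8 arrays gave as many called lists.

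In WIN1SRDX seedlings too, most cutin and wax genes were lower than in wild type, as were 6 of 12 suberin and 7 of 17 expansin genes, and 4 of 7 senescence genes rose. These lists were called by camera at its preset correlation, and none with an estimated correlation (lowest adjusted p = 0.237 with an estimated correlation). CER2, a wax elongation factor, changed by -6.46 ± 0.72 (SE, adjusted p = 0.000167, above background on 3 of 4 WIN1SRDX arrays) and the elongase KCS1 by -3.89 ± 0.44 (SE, adjusted p = 0.000197). bHLH39 and BHLH101, transcription factors of the iron deficiency response, rose by 6.94 ± 1.73 (SE, adjusted p = 0.0113) and 5.62 ± 0.99 (SE, adjusted p = 0.00196).

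Between WIN1SRDX and wild type 6606 genes (32.6%) differed, 3528 higher and 3078 lower, and 2967 of them at least 2-fold. In 43% of genes the arrays of the groups did not overlap, against 2.86% by chance. With the slide as a block 5730 genes differed. On the authors' own scale, which divides each group by a constant, 3982 were higher and 2005 lower, so that 66.5% of calls were rises, against 53.4% here.

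Among genes well above background on all arrays of both groups, the largest rises besides those of bHLH39 and BHLH101 (5.62) were those of MSRB8 (6.57 ± 0.50, SE), PXMT1 (6.14), DXPS1 (5.99), CYP76C2 (5.80), SAG13 (5.74) and the thionin THI2.1 (5.38). Among the same fully measured genes the largest falls were those of NEET, an iron-sulfur cluster protein (-6.12 ± 1.17, SE), PRP4 (-5.27), ESP, which steers glucosinolate breakdown (-5.14), and GSTF14 (-4.99). DCF, an acyltransferase that feruloylates cutin, changed by -4.94, ABCG19 by -4.90, ABCB14 by -4.87 and MYB96, an activator of wax genes, by -4.64.

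Of 22 cutin genes, 15 fell and none rose, with 18 falls adjusted over the list alone (median -2.53, adjusted p = 1.75e-06; adjusted p = 0.462 with an estimated correlation). GPAT4 changed by -3.23 ± 0.49 (SE), GPAT6 by -2.44, CYP86A4 by -2.52 and LTPG1, a lipid transfer protein, by -3.91. Of 22 wax genes, 17 fell and none rose, with 18 falls adjusted over the list alone (median -2.80, adjusted p = 1.6e-06; adjusted p = 0.462 with an estimated correlation). KCS9 and KCS20 changed by -1.26 and -2.25. Suberin genes fell in 6 of 12 cases, 7 adjusted over the list alone (median -1.55, adjusted p = 0.000637; adjusted p = 0.462 with an estimated correlation), with FAR1 at -3.98, FACT at -2.60, ABCG2 at -1.92 and FAR5 at -1.46. Within slides 1, 2 and 3 the cutin median was -2.38, -1.29 and -3.99, the wax median -2.57, -1.24 and -4.13, and the suberin median -1.55, -2.21 and -1.44.

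Among 13 cuticle regulators 7 fell and 1, WIN1 itself, rose, also adjusted over the list alone (median -1.14, mean -0.44; adjusted p = 0.0318; adjusted p = 0.462 with an estimated correlation). WIN1 signal, not separated from that of the transgene, enters these list tests. Without WIN1SRDX replicate 1 the median was -0.86 and the list was no longer called (adjusted p = 0.0559). The epidermal factors ATML1 and PDF2 changed by -2.79 and -2.18. MYB106 changed by -1.60 ± 0.54 (SE, adjusted p = 0.0437), a call lost without any of 8 single arrays (-1.70 to -1.32, adjusted p from 0.0514 to 0.115) and with the slide as a block (adjusted p = 0.0843). MYB16 changed by -3.23 ± 1.04 (SE, adjusted p = 0.0354), lost without any of 6 single arrays (-3.32 to -2.31, adjusted p from 0.0684 to 0.08) and with the slide as a block (adjusted p = 0.0639). SHN2 differed by -1.14 ± 1.18 (SE, adjusted p = 0.484).

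Expansins fell in 7 and rose in 1 of 17 cases, 8 and 1 adjusted over the list alone (median -1.24, adjusted p = 0.0267; adjusted p = 0.675 with an estimated correlation). The expansin call was lost with only genes well above background on all 12 arrays (adjusted p = 0.0529) and with fry (adjusted p = 0.0537). EXPA16 changed by -5.26, EXLA2 by -2.19 and EXPA9 by 1.80. Cell cycle genes rose in 4 of 21 cases, and in 4 adjusted over the list alone (median 0.52, adjusted p = 0.0315; adjusted p = 0.759 with an estimated correlation). The cell cycle call was lost with fry (adjusted p = 0.205) and without WIN1SRDX replicate 2 or wild-type replicate 1 (medians 0.47 and 0.46, adjusted p from 0.0591 to 0.0764). The risers were replication genes: TSO2, a ribonucleotide reductase, at 2.01, PCNA1 at 0.97, MCM2 at 0.90 and MCM5 at 0.73. Senescence genes rose in 4 of 7 cases, and in 4 adjusted over the list alone (median 0.67, adjusted p = 0.0119; adjusted p = 0.237 with an estimated correlation), with SAG29 at 2.93 and SAG21 at 0.67.

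The other lists were not called in WIN1SRDX. Root markers rose in 7 and fell in 5 of 17 cases (8 and 7 adjusted over the list alone; median 0.66, mean -0.12; adjusted p = 0.548), with PRP1 at 3.34, TIP2;3 at -5.99 and CASP5 at least 8.37-fold lower. Salicylic acid defence genes rose in 4 and fell in 1 of 14 (5 and 1 adjusted over the list alone; median 0.71, adjusted p = 0.0705), with CYP71A13 at least 28.6-fold higher, PAD3 at 4.19 and PBS3 at 1.98. The list was called without MYB106SRDX replicate 2 (adjusted p = 0.0282), with array weights (adjusted p = 0.0297), with only the groups compared (adjusted p = 0.0216) and by fry (adjusted p = 0.00794). Clock genes fell in 9 and rose in 4 of 15, in the same numbers adjusted over the list alone (median -0.61, mean 0.05; adjusted p = 0.132; fry, adjusted p = 0.0044), with TOC1 at -1.54, GRP7 at -2.38 and GRP8 at -1.18. Touch and wounding genes fell in 4 of 14 (3 adjusted over the list alone; median -0.46, adjusted p = 0.0624), among them XTH22 at -1.55, TCH3 at -1.34 and ERF6 at -1.86. The list was called without any of 4 single arrays (-0.70 to -0.46, adjusted p from 0.0168 to 0.0484), with normexp (adjusted p = 0.0449) and on the authors' scale (adjusted p = 0.0225). Jasmonate genes fell in 5 and rose in 3 of 24, as adjusted over the list alone (median -0.48, adjusted p = 0.298), with LOX3 at -4.04, LOX4 at -2.79 and HEL at 2.03. Abscisic acid and drought genes fell in 4 and rose in 1 of 19 (6 and 1 adjusted over the list alone; median -0.93, adjusted p = 0.132), with RD22 at -4.12, COR47 at -0.93 and HB-7 at 1.52. The list was called without MYB106SRDX replicate 2 (adjusted p = 0.0282), on the authors' scale (adjusted p = 0.0411) and with only the groups compared (adjusted p = 0.0445). Trichome genes fell in 2 (HDG2 at -2.68 and SIM at -1.02) and rose in 1 (GL3 at 1.43) of 16, also adjusted over the list alone (median -0.20, adjusted p = 0.254), while MYB23 at -1.77 did not pass. MYB23 passed with normexp (adjusted p = 0.031), quantile normalization (adjusted p = 0.0398), array weights (adjusted p = 0.0216) and only the groups compared (adjusted p = 0.00365), and without either of 2 single arrays (adjusted p from 0.00991 to 0.028). The SIM call was lost with the slide as a block (-0.92, adjusted p = 0.0546). It was also lost without either of 2 single arrays (-0.91 and -0.87, adjusted p from 0.0596 to 0.0691). The GL3 call was lost without wild-type replicate 1 (1.23, adjusted p = 0.051). Stomatal genes fell in 3 (SDD1 at -3.87, KAT1 at -1.69 and TMM at -2.63) and rose in 1 (ERL2 at 1.44) of 18, also adjusted over the list alone (median -1.59, adjusted p = 0.145; -1.89 and adjusted p = 0.0387 without WIN1SRDX replicate 2). The KAT1 call was lost without any of 4 single arrays (adjusted p from 0.0515 to 0.0629). Flavonoid genes fell in 3 (TT8 at -2.23, MYB111 at -3.18 and UGT75C1 at -1.84) and rose in 1 (MYB12 at 0.99) of 17, also adjusted over the list alone (median -0.74, adjusted p = 0.279), and the MYB111 call was lost without any of 5 single arrays (adjusted p from 0.0506 to 0.0592). Photosynthesis genes fell in 3 and rose in 1 of 20 (2 and 1 adjusted over the list alone; median -0.20, adjusted p = 0.145), with RBCS2B at -0.93, RBCS1B at 1.49 and LHCB1.3 at -1.71. The LHCB1.3 call was lost with the slide as a block (-1.67, adjusted p = 0.0501) and without either of 2 single arrays (adjusted p from 0.0522 to 0.0529). No aliphatic glucosinolate gene passed of 14 (also adjusted over the list alone; median 0.04, adjusted p = 0.897), and of 13 flowering markers AGL24 rose by 1.06 (none adjusted over the list alone; median 1.06, adjusted p = 0.298). The mean of the flowering markers relative to wild type was 2.26 and 2.16 on WIN1SRDX replicates 2 and 3 and -0.57 and -0.49 on replicates 1 and 4, and their median within slides 1, 2 and 3 was 0.18, 3.11 and 0.35. Camera called 7 of 19 lists, none with an estimated correlation, and 19 of the 35 splits of the 8 arrays gave as many.

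**Figure D2:**
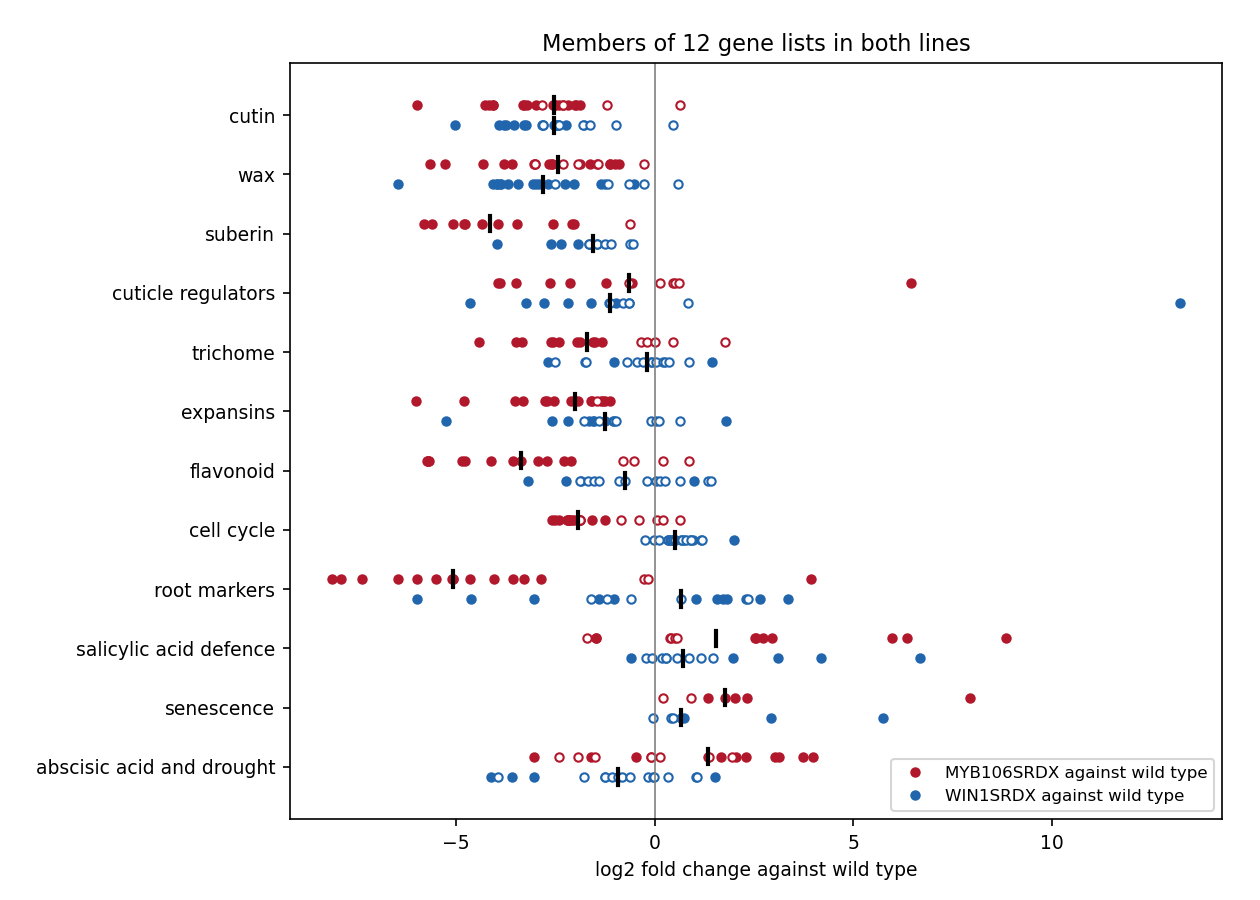
Log2 fold change against wild type of each tested member of 12 gene lists in MYB106SRDX (red) and WIN1SRDX (blue); filled circles passed adjusted p under 0.05, open circles did not, and the black bar is the median. Cutin and wax medians lay between -2.80 and -2.44 in both lines, whereas root marker medians were -5.08 in MYB106SRDX and 0.66 in WIN1SRDX.

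Both lines shared lower transcripts of cutin and wax genes. PRP4 (-6.29 in MYB106SRDX and -5.27 in WIN1SRDX), the auxin response gene IAA19 (-5.50 and -4.59), MSRB6 (-7.0 and -4.41) and the fatty acyl reductases FAR8 (-4.19 and -4.48) and FAR1 (-3.95 and -3.98) were lower in both. KDR, a small helix-loop-helix factor (-4.47 and -3.85), the lipid transfer gene LTPG2 (-4.07 and -3.80) and GPAT8 (-5.98 and -3.75) completed the 8 strongest. MSRB8 (6.18 and 6.57), PXMT1 (8.79 and 6.14), DXPS1 (7.52 and 5.99), CYP76C2 (9.16 and 5.80), SAG13 (7.93 and 5.74), ABCG40 (8.83 and 5.30), the trypsin inhibitor TI1 (6.69 and 5.08) and the acetyltransferase NATA1 (6.62 and 5.01) were the strongest among genes higher in both.

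Of the tested genes, 1859 were lower in both lines and 2110 higher in both, while 146 were higher in MYB106SRDX and lower in WIN1SRDX and 299 the reverse. Independent lists of these sizes would share 880.6, 833.7, 727.3 and 1009 genes. Simulations without group differences, in which the wild-type arrays were redrawn too, shared on average none in either direction. Hardly any gene is called where no group differs. This value therefore cannot show how far shared controls raise the overlap of lists as long as these. With the wild-type arrays split so that each line had controls of its own, 897 to 998 genes were lower in both and 1109 to 1216 higher in both, over 6 ways to split them. There 26 to 76 genes were higher in MYB106SRDX and lower in WIN1SRDX and 100 to 188 the reverse. Each line then had fewer control arrays, and the overlap of independent lists was not computed for these fits. The split counts are thus not comparable with 880.6 and 833.7. Across genes, which are not independent replicates, the fold changes of the lines correlated at r = 0.55 (Spearman 0.48), with 0.50 from simulated unchanged groups and 0.51 to 0.56 with split controls. Their covariance was 0.962, with 0.0756 from simulation, a difference of 0.886. With the slide as a block 1571 genes were lower and 1781 higher in both.

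By list, 14 of 22 cutin, 12 of 22 wax, 5 of 12 suberin and 6 of 17 expansin genes were lower in both lines. Clock genes were lower in both in 8 of 15 cases and higher in both in 2, LHY (2.53 and 3.53) and CCA1 (2.26 and 3.14), which encode morning-phased factors and were named after their values were seen. Evening-phased TOC1 was lower in both (-0.66 and -1.54). The clock list had been fixed as a sign of harvest time. Only 4 of its 15 genes in MYB106SRDX and 2 in WIN1SRDX did not pass, while 52.2% and 32.6% of all tested genes differed. A difference in harvest time or clock phase between wild type and both lines was not separated from the transgenes. Such a difference would also enter the counts of shared genes. Among root markers 5 were lower in both and 6 moved in opposite directions.

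**Figure D3:**
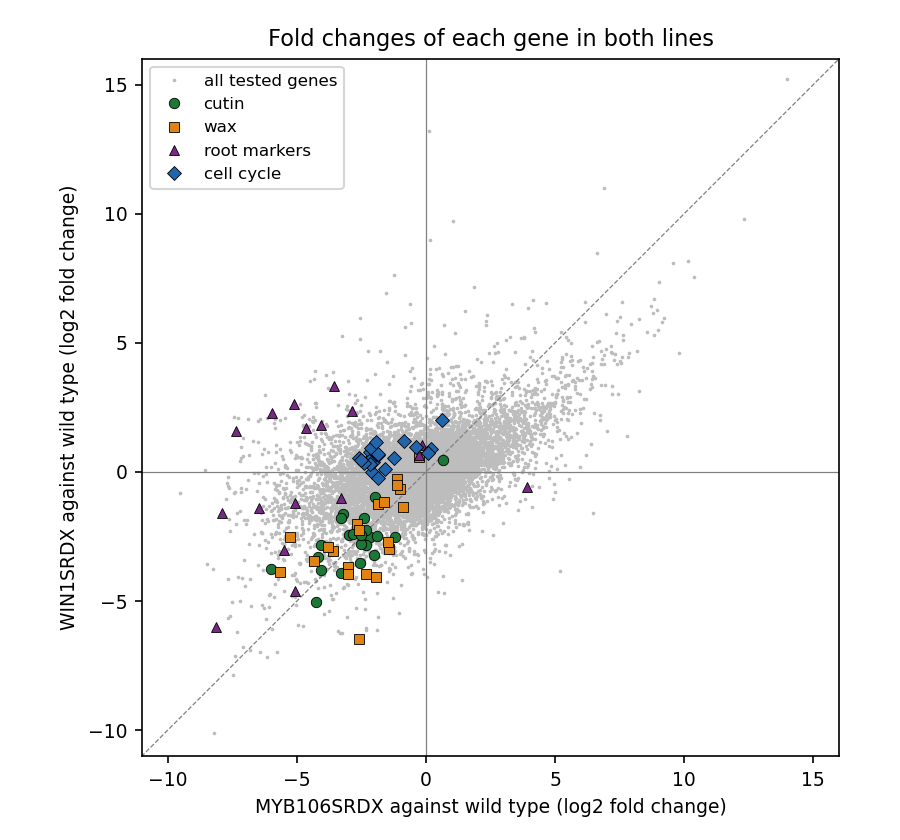
Log2 fold change against wild type in WIN1SRDX (vertical axis) against that in MYB106SRDX (horizontal axis) for 20267 tested genes, with cutin, wax, root marker and cell cycle genes marked. Of the cutin and wax genes 14 and 12 of 22 were called lower in both lines (lower left), while 6 of 17 root markers were called in opposite directions.

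Set against each other, the lines differed by the lowest camera p in root marker and cell cycle genes, while no cutin gene passed. Neither list was called with an estimated correlation (adjusted p = 0.272 and adjusted p = 0.642 with an estimated correlation). Of 22 cutin genes none passed (none adjusted over the list alone; median -0.07, adjusted p = 0.947), with HTH at -1.58 ± 0.60 (SE, adjusted p = 0.0544), CYP86A8 at -1.53, GPAT4 at 1.23 and ABCG11 at 1.33. Some of these passed in other settings: HTH without any of 3 single arrays (-2.0 to -1.86, adjusted p from 0.0218 to 0.0448), CYP86A8 without either of 2 (-2.12 and -1.79, adjusted p from 0.00421 to 0.0477), GPAT4 without 1 (1.70, adjusted p = 0.00661) and ABCG11 without 1 (1.78, adjusted p = 0.0286). On the authors' scale HTH (adjusted p = 0.0316) and CYP86A8 (adjusted p = 0.0346) passed, and with quantile normalization GPAT4 did (adjusted p = 0.0314). The cutin median was -1.06, -1.01 and 1.48 within slides 1, 2 and 3, so whether the lines differ in cutin genes stays open. Of 22 wax genes, 3 were lower in MYB106SRDX (KCR1 at -0.86, PAS2 at -0.60 and KCS9 at -0.61) and 1 was higher (CER2 at 3.87), with 2 and 1 adjusted over the list alone (median -0.42, mean 0.08; adjusted p = 0.979). Root markers were lower in MYB106SRDX in 15 of 17 cases and higher in 1, also adjusted over the list alone (median -5.05, -4.87 with bounds; adjusted p = 1.28e-07; adjusted p = 0.272 with an estimated correlation). COBL9, EXPA18 and PRP1 were at least 129.3-fold, 82.1-fold and 29.2-fold lower.

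In all 8625 genes (42.6%) differed between the lines, 3717 higher and 4908 lower in MYB106SRDX, and 4860 at least 2-fold. In 34.7% of genes the arrays did not overlap, against 2.86% by chance. With the slide as a block 8065 genes differed. On the authors' own scale 2064 were higher and 6002 lower, a share of 25.6% rises against 43.1% here.

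Beyond MYB106 (8.06 ± 0.54, SE), the fully measured genes most raised in MYB106SRDX over WIN1SRDX were MYB74 (5.46), M17 (5.42), WRKY30 (5.29), MYB96 (5.09), TDR1 (4.97), GATL2 (4.76) and the lipoxygenase LOX3 (4.72). The most lowered of these were DR4 (-6.55), BHLH101 (-6.43), the root hair wall enzyme XTH14 (-5.88), SBT4.12 (-5.76), the auxin-induced SAUR63 (-5.24), GATA12 (-5.09) and the auxin response repressor AXR3 (-5.08).

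Cell cycle genes were lower in MYB106SRDX in 20 of 21 cases, also adjusted over the list alone (median -2.50, adjusted p = 1.26e-06; adjusted p = 0.642 with an estimated correlation), with CDKB1;1 at -2.74, PCNA1 at -1.37 and CYCB2;1 at -3.05. Within slides 1, 2 and 3 the root median was -4.94, -3.39 and -6.03 and the cell cycle median -2.04, -3.92 and -0.54. The trichome median there was -1.70, -2.61 and 0.122 and the expansin median -1.21, -2.77 and 0.565. Within slide 3, with 1 array of each line, neither the trichome nor the expansin median was lower in MYB106SRDX. Flavonoid genes were lower in 10 of 17, and in 10 adjusted over the list alone (median -3.61, -2.80 with bounds; adjusted p = 0.000741; adjusted p = 0.642 with an estimated correlation), with the chalcone synthase gene CHS at -4.67, F3H at -3.72 and MYB12 at least 13.9-fold lower. Suberin genes were lower in 9 of 12 (9, and 1 higher, adjusted over the list alone; median -1.86, adjusted p = 0.0104; adjusted p = 0.69 with an estimated correlation), with ABCG2 at -1.56, ABCG6 at -3.16, CYP86B1 at -4.16 and ASFT at -3.73. This difference, like that of the trichome genes below, was not separated from one in the share of roots. Trichome genes were lower in 8 and higher in 2 (MYB5 at 1.18 and HDG2 at 1.35) of 16, or 10 and 2 adjusted over the list alone (median -1.58, adjusted p = 0.0457; adjusted p = 0.69 with an estimated correlation). The trichome call was lost without any of 6 single arrays (adjusted p from 0.0542 to 0.0962) with the slide as a block (-1.47, adjusted p = 0.0671), with normexp (-0.31, adjusted p = 0.15), with quantile normalization (-1.29, adjusted p = 0.0757), with array weights (-1.20, adjusted p = 0.14), on the authors' scale (-1.75, adjusted p = 0.105) and with only genes well above background on all 12 arrays (-0.93, adjusted p = 0.183). CPC changed by -1.59, GIS by -2.10 and EGL3 by -2.75, and ETC2 was at least 2.03-fold lower, a call lost under the other background correction (-0.18, adjusted p = 0.517). Expansins, among them EXPA9 at -3.14, EXPA11 at -4.47 and EXPA6 at -2.10, were lower in 8 and higher in 1 of 17, also adjusted over the list alone (median -1.75, adjusted p = 0.0694). Without either of 2 single arrays the list was called (-2.48 and -2.23, adjusted p from 0.00441 to 0.045), as it was with normexp (adjusted p = 0.0203), no filter on dim probes (adjusted p = 0.0329), only genes well above background on all 12 arrays (adjusted p = 0.0252) and fry (adjusted p = 0.0259).

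Abscisic acid and drought genes were higher in MYB106SRDX in 10 of 19, and in 10 adjusted over the list alone. Their median was 1.66 (camera, adjusted p = 0.000741, and adjusted p = 0.657 with an estimated correlation). HAI1 stood at 3.97, RD26 at 1.96 and ABI1 at 1.71. On MYB106SRDX replicate 2 the mean of this list relative to wild type was -1.227, within the WIN1SRDX range of -1.419 to -0.6812. Touch and wounding genes were higher in 10 and lower in 1 of 14, also adjusted over the list alone (median 1.40, adjusted p = 0.00162; adjusted p = 0.642 with an estimated correlation), with WRKY40 at 2.72, SZF2 at 1.86 and TCH3 at 1.09. Jasmonate genes were higher in 9 and lower in 3 of 24, or 10 and 4 adjusted over the list alone (median 0.58, adjusted p = 0.0457; adjusted p = 0.76 with an estimated correlation). The jasmonate call was lost without any of 3 single arrays (adjusted p from 0.0846 to 0.176), with normexp (adjusted p = 0.0757), with quantile normalization (adjusted p = 0.088), with array weights (adjusted p = 0.0541) and with only genes well above background on all 12 arrays (adjusted p = 0.0707). LOX4 stood at 4.19 and ORA59 at -2.31. Senescence genes were higher in 5 and lower in 1 of 7, also adjusted over the list alone (median 1.3, adjusted p = 0.0104; adjusted p = 0.272 with an estimated correlation), with ORE1 at 1.84, NAP at 1.3 and NYE1, which starts chlorophyll breakdown, at 1.36.

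The other lists were not called between the lines. Among 13 cuticle regulators 3 were higher (MYB106, MYB96 and HDG1) and 3 lower (WIN1, DEWAX and MYB41), also adjusted over the list alone. Their median was 0.08 and their mean -0.36 (camera, adjusted p = 0.686). MYB106 and WIN1 signals, not separated from those of the transgenes, enter this test. Salicylic acid defence genes were higher in 2 (PR1, at least 15.6-fold, and PR5) and lower in 3 (PAD4 at -0.87, WRKY38 at -3.19 and WRKY70) of 14, also adjusted over the list alone (median 0.42, adjusted p = 0.662). Stomatal genes were lower in 4 of 18 (3 adjusted over the list alone; median -0.15, adjusted p = 0.686), among them EPFL9 at -2.12 and ER at -1.26. Clock genes were higher in 3 and lower in 2 of 15, also adjusted over the list alone (median 0.23, mean -0.20; adjusted p = 0.662), with RVE1 at -2.36, TOC1 at 0.88 and ELF3 at 0.53. The ELF3 call was lost on the authors' scale (0.37, adjusted p = 0.147), without replicate 2 of both lines (0.39, adjusted p = 0.0631) and with only the groups compared (adjusted p = 0.058). Flowering markers were lower in 3 of 13, also adjusted over the list alone (AGL24 at -1.41, SOC1 at -1.26 and SPL3 at -1.69; median -1.27, adjusted p = 0.381). Aliphatic glucosinolate genes were lower in 3 of 14 (2 adjusted over the list alone; UGT74C1 at -1.25, GSTF11 at -2.16 and CYP79F2 at -1.08; median -0.30, adjusted p = 0.662), and photosynthesis genes were higher in 1 (RBCS2B) of 20 (none adjusted over the list alone; median -0.14, adjusted p = 0.686). The calls of CYP79F2, KCS9, SOC1, SPL3 and TGG2 in this comparison were each lost without some single arrays, and these and PAS2 (adjusted p from 0.0523 to 0.0768) with only the groups compared. CYP79F2 was also lost with the slide as a block (-0.93, adjusted p = 0.0602), with normexp (-0.51, adjusted p = 0.0738) and with quantile normalization (-0.63, adjusted p = 0.151). TGG2 was also lost with array weights (-1.44, adjusted p = 0.0703) and without replicate 2 of both lines (-1.25, adjusted p = 0.0801). Camera called 9 of 19 lists, none with an estimated correlation, and 11 of the 35 splits of the 8 arrays gave as many.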

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

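The tests on probe scale and on the spread of root transcripts were chosen only after the results were seen, while the tests on other splits and the second root list had their predictions written before their values were computed.

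Root transcripts in MYB106SRDX were lower than in wild type and than in WIN1SRDX, with a median difference between the lines of -5.05. A second root list, of other cell types and transporters, had a median of -2.50 against wild type, with 12 of 19 genes lower, 2 higher (PHT1;4 at 1.80 and THAS1 at 1.95) and 5 not passing; a smaller share of root tissue may therefore contribute and is left undecided by this value. The root transcripts were not all lowered alike: over 36 members of both lists the SD of the fold changes was 2.76 against a median SE of 0.431. Of these, 26 were lower, 3 higher and 7 did not pass. Members near background or also present in other organs would fall less, so this spread cannot decide whether the share of roots was smaller. A lower signal scale was excluded, as the median over all tested genes before scaling was -0.323. Whether MYB106SRDX acts on root genes directly was not tested, and root mass is not given in the sources used here.

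Other lists also differed between the lines by a test of the difference itself (camera). Their median log2 differences, MYB106SRDX minus WIN1SRDX, were -3.61 for flavonoid, -2.50 for cell cycle, -1.86 for suberin and -1.58 for trichome genes, and 1.66 for abscisic acid and drought, 1.40 for touch and wounding, 1.3 for senescence and 0.578 for jasmonate genes. With an estimated correlation none of these was called.

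A single array stood far from the other 3 of its group in some measures (Dixon's test). This was so for 1 of 21 array measures, 2 of 57 list means and 18 of 426 named genes (4.76%, 3.51% and 4.23%), where chance gives about 1 in 20. WIN1SRDX replicate 2 had 181 spots marked as outliers, against 2 to 9 on the other arrays of its group. In MYB106SRDX replicate 2 the mean of the salicylic acid defence list relative to wild type was 1.326 (others 2.297 to 2.4) and that of the abscisic acid and drought list -1.227 (others 1.289 to 1.452).

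MYB106SRDX replicate 2 was also apart in MYB106 (2.772), in the abscisic acid genes HAI1 (0.8141) and RD26 (2.667), and in the clock genes ELF3 (2.054) and TOC1 (1.009). In replicate 1 of that line CYP86A4 read -1.978 (others -4.033 to -3.949), and in replicate 4 XTH22 read 2.575. In WIN1SRDX replicate 1, CHS read -2.038, FAR8 -7.178 and SHN2 -6.641. SZF2 read 1.693 in WIN1SRDX replicate 2 and ERF6 -3.671 in replicate 4. In wild-type replicate 2, CER2 read 1.006, GIS -0.4151, MSRB8 -6.351 and MYB96 1.314. HB-7 read 1.897 in wild-type replicate 1 and TOC1 1.116 in replicate 3.

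Probes that name no locus carried signal as well. Of 2499 such probes tested, 437 were higher than wild type in MYB106SRDX and 622 lower, and in WIN1SRDX 241 were higher and 556 lower; 152 were higher and 325 lower in both lines. What these probes measure was not analysed here.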

How the results depend on the processing

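All alternatives were planned except normexp on the median signal, added when the files were seen to give no mean signal, and a floor at the background limit and leaving out 2 arrays of doubt; tests with these were chosen only after the data were seen. No result reversed. Over all settings 6291 values of named genes kept their side of the threshold, 72 became weaker and 19 stronger. For list medians these were 1546, 68 and 39. A gene not tested under a setting is not counted there. With only genes well above background on all 12 arrays, 195 named values kept their side, against 238 with the mean of probes. Leaving out an array that is not part of a comparison also leaves its fold changes as they were. With any single array left out, 9167 to 10807 genes differed between MYB106SRDX and wild type, 4850 to 7465 between WIN1SRDX and wild type and 7720 to 8659 between the lines. Cutin medians then ranged from -2.99 to -2.31 and from -3.12 to -2.23 against wild type, and wax medians from -2.88 to -2.07 and from -3.22 to -2.19. A 2-fold threshold left 5765, 2967 and 4860 genes by its own construction, with 946 lower and 801 higher in both lines. With an estimated correlation camera called 0, 0 and 0 lists; the cutin and wax medians stayed at -2.54 and -2.44 in MYB106SRDX (adjusted p = 0.537 and 0.528) and at -2.53 and -2.80 in WIN1SRDX (adjusted p = 0.462 for both), since only the variance of the list differs there.

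Normexp gave 9818, 6506 and 7819 genes, quantile normalization 10541, 6896 and 8669, and array quality weights 11350, 8768 and 7077. The authors' value table gave 9421, 5987 and 8066, with median shifts of -0.10, 0.12 and -0.20 that come from its constants per group. Leaving out replicate 2 of both lines gave 11046, 7192 and 8030. With the replicate number as a block these were 10031, 5860 and 8013; arrays of a number correlated between -0.16 and 0.20, and 3 of 12 matched their own number best, so the numbers were not read as pairs. PRR5 in MYB106SRDX no longer passed with marked spots kept (-1.46, adjusted p = 0.0673) or on the authors' scale (-1.51, adjusted p = 0.0785), and the cause was not tested. The planned normexp on the mean signal and the scan date as a block were not run, as the files hold no mean signal and 1 scan date. Genes near background limit the bounds, as for ETC2 and MYB41.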

Other observations

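The tests on SUP and the one on the second iron list without BHLH101 were chosen only after the results were seen, while the tests on single deviating arrays and on other splits had their predictions written before their values were computed.

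Some iron deficiency genes rose in WIN1SRDX and others fell, and no test against other genes was run on them. The transcription factor genes bHLH38 and BHLH100 rose by 9.71 ± 1.88 (SE, adjusted p = 0.00313) and 8.97 ± 1.59 (SE, adjusted p = 0.00204), each well above background on 2 of 4 wild-type arrays. The 3 ferritin genes, which encode iron stores, fell: FER1 by 3.05, FER3 by 2.27 and FER4 by 3.19 (median -3.04). In MYB106SRDX only replicate 4 was high in these factors: bHLH38 read 1.40 against -9.13, -8.44 and -6.52 on replicates 1, 2 and 3, bHLH39 read 0.62 against -8.37, -9.19 and -7.70, and BHLH100 read -0.62 against -8.64, -9.30 and -6.14. In that line 1 ferritin gene fell (median -0.99), and between the lines 2 were higher in MYB106SRDX (median 2.2).

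An iron deficiency response in WIN1SRDX may underlie this and stays open. In a second list of iron genes, taken without BHLH101 because that gene was already among those seen to rise, the median was 2.3: of 10 genes 6 rose (IMA1 5.76, OPT3 3.1, ORG1 2.86, BTS 2.54, PYE 2.07 and FRO3 1.46), NAS4 (3.25, adjusted p = 0.0512) did not pass, and FRO2 (-1.70), CYP82C4 (-4.23) and COPT2 (-0.97) fell. IRT1, the iron uptake transporter gene that iron deficiency induces, also fell (-3.04, adjusted p = 0.00752), which goes against such a response. A single deviating array was excluded as the cause, since the mean rise of bHLH38, bHLH39 and BHLH100 was at least 8.36 with any WIN1SRDX array left out. In MYB106SRDX 4 of the 11 genes with BHLH101 rose and 4 fell (median -0.59), and 10 were lower than in WIN1SRDX (median -1.64); iron content is not given in the sources used here.

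SUP signal was high in both lines. It may come from the repression domain of the transgenes, since in MYB106SRDX the SD of SUP minus MYB106 was 0.0951 of the SD of SUP (0.0834 against 0.877). SUP read 5.34, 3.59, 5.46 and 5.17 on MYB106SRDX replicates 1 to 4 and 6.15, 6.06, 5.93 and 6.37 on those of WIN1SRDX. The plant's own SUP gene restricts AP3 and PI in flowers, but neither gene fell in either line. PI rose by 3.48 in MYB106SRDX (adjusted p = 0.0164) and stood at 2.70 in WIN1SRDX without passing (adjusted p = 0.0695). AP3 stood at 2.56 and 3.39 and did not pass (adjusted p = 0.273 and 0.188). AP3 was well above background on only 2 of 4 wild-type arrays. The rise of PI alone cannot decide whether the plant's own SUP gene was induced, since AP3 did not pass and AG was not tested. Induction of SUP thus stays open in both lines. Where the probe lies was not used here.

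The second root list in WIN1SRDX had 4 genes higher and 4 lower than wild type (median 0.35), and between the lines 13 of its 19 genes were lower in MYB106SRDX (median -2.66).

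The 8 arrays of each comparison were also divided in every other way, and the 12 arrays in a sample of other ways. Of the 35 splits of 8 arrays, only the real one (1) called as many genes in each comparison: 10587 genes against at most 1 for MYB106SRDX and wild type, 6606 against at most 3 for WIN1SRDX and wild type, and 8625 against at most 83 between the lines. Called lists were as many or more in 14 of 35 splits for MYB106SRDX (10 lists, at most 14), 19 of 35 for WIN1SRDX (7 lists, at most 14) and 11 of 35 between the lines (9 lists, at most 12), so chance is not excluded for the number of called lists. Of 100 splits of all 12 arrays, only the real one (1) gave as many genes lower in both lines (1859, at most 1319 otherwise) and higher in both (2110, at most 1567 otherwise). The split with 1319 and 1567 kept all 4 wild-type arrays as controls and only mixed the lines. Every remaining split gave at most 2 genes lower and 1 higher in both.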
